A study of Mus musculus with 25 samples.

How the data were processed

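Total RNA of prefrontal cortex was sequenced from 25 samples in 6 groups, 13 male and 12 female, per the labels. A table of all samples was used. It names its 25 columns by a letter and a number, and the letters occur in no sample label. Numbers up to 5 occur under 1 letter, and 1 group has titles numbered up to 5, the stressed vehicle-treated males. These 5 columns were assigned to that group by number, which assumes that letters stand for groups and numbers for replicates. The other 20 columns match 5 groups equally well by name. They were not assigned by order or values and were not used here. The comparisons planned before the data were examined (stress, treatment and their interactions with sex, sex in controls, and treated mice against controls) were therefore not run.

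The deposited values are on a log2 scale. Per the submitters' processing notes, the tools included STAR 2.6.1d, SAMtools 1.9, featureCounts from Subread 1.6.3 and edgeR, with the builds mm10 and GRCm38. The annotation release, strandedness and gene filter are not given in the sources used here, so reads of a gene and of an overlapping antisense gene are not told apart. The form of the values was inferred from the values themselves, as log2 of a read number plus 0.5, scaled to CPM with an effective library size. With the lowest value of a column taken as 0 reads, 100% of the values in each library came out whole within a tolerance of 1e-06 reads. The effective size was 0.998 to 1.04 times the summed reads.

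Reads and CPM were computed from the deposited log2 values (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). RPKM divides CPM by the union exon length in GENCODE M21 on GRCm38, the source of the coordinates. Symbols were matched for 23846 of 23990 identifiers. Library totals were 34565147 to 44265039 reads, so that 3 reads correspond to 0.0673 to 0.0870 CPM. Reads are not shown to be independent molecules, so floors and chi-square tests cover counting error only. Every pair of libraries differed beyond counting error, in at least 4950 genes, and no library was counted as a duplicate.

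Variation beyond counting error was tested per gene with a chi-square test that reads were proportional to effective library size (4 degrees of freedom, Benjamini-Hochberg over genes with a mean of at least 5 reads). The test was checked on simulated reads of 19148 genes with 200 made variable. It recovered 63% of genes with a coefficient of variation of 20% and 80% of those with 50%, and called 3 unchanged genes. Above 100 reads it recovered 85.9% and 100%. In the data 14308 genes were called, far more than the 200 made variable, so these shares need not hold there. A total of 32 gene lists (680 genes, 666 in the table) was fixed before the data were examined. A list score is the mean, over members with at least 1 CPM, of log2 expression less the gene's mean over libraries, for lists with at least 3 such members. Its SD was set against 10000 random lists drawn from the 200 genes nearest in level to each member. In simulations, 20 of 20 lists with a log2 shift of 0.3 in 1 library passed the 95th percentile, as did 2 of 20 unshifted lists. Genes varied independently in these simulations, which therefore do not calibrate the percentile for lists of genes that vary together.

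The planned rule for named genes rests on comparisons between groups. It was replaced, before any gene's value was looked at, by Il6, Rac1, Fkbp5, Bdnf, Xist and 4 Y-linked genes fixed earlier, the 3 most abundant members and the most variable member of each list, the 10 most abundant genes, and the 10 genes with the largest SD over a running median of 501 genes of like level. Alternatives were scaling to total reads or by median of ratios, 0.1 or 2 reads added before the log, other filters on low values, removal of GC and length trends, and leaving out each replicate. Another 2 lists of cortical layer genes and 4 of meningeal, red blood cell, neutrophil and endothelial acute-phase genes were written after the first results were seen. Members of these lists and of their random lists had a mean of at least 0.5 CPM. Genes named from these added lists alone were chosen after their values were seen. Some genes that the rule selects are not reported here.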

Results

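The study profiled total RNA of the prefrontal cortex of C57BL/6 mice aged 10 weeks by RNA sequencing in 6 groups. Mice of each sex were controls, went through social defeat with vehicle, or went through social defeat under treatment with dihydrocaffeic acid and malvidin-glucoside, a pair of plant phenolic compounds. Social defeat is a procedure in which a mouse is stressed by exposure to an aggressor. The design asks what stress changes in each sex and what the compounds change under stress. Of 25 samples, the 5 libraries of stressed, vehicle-treated males (replicates 1 to 5) could be tied to the labels by name, and the 5 other groups were not analysed here. The values therefore describe the prefrontal cortex of stressed males and the spread between these libraries, and hold no effect of stress, treatment or sex. The assignment reads the letter of a column name as the group and its number as the replicate. The labels do not say that each library came from a separate animal, so the spread may be partly technical.

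The libraries held 34565147 to 44265039 reads assigned to genes. Between 21790 and 22277 of the 23990 listed genes had reads in a library, and 14524 genes had a mean of at least 1 CPM. Values with an error are means ± SD over libraries (n = 5). Mitochondrial messages were the most abundant, with the cytochrome oxidase gene mt-Co1 at 17971 ± 656 CPM, mt-Cytb at 8031 ± 396 CPM and mt-Nd1 at 7166 ± 288 CPM. Among nuclear genes the neuronal kinesin Kif5a (5568 ± 581 CPM), the astrocytic glutamate transporter Slc1a2 (4112 ± 177 CPM) and the noncoding RNA Meg3 (3842 ± 866 CPM) stood highest.

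The Y-linked genes Ddx3y (49.9 ± 2.71 CPM), Eif2s3y (41.7 ± 4.31 CPM), Kdm5d (25.1 ± 2.84 CPM) and Uty (12.3 ± 1.10 CPM) were expressed in each of the 5 libraries, which carry the male label. Xist, the noncoding RNA that silences an X chromosome in female cells, stood at 0.170 ± 0.0796 CPM. The X-linked partners Ddx3x, Kdm5c and Eif2s3x were at 207 ± 14.7, 50.5 ± 2.98 and 47.4 ± 4.17 CPM.

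Il6 and Rac1 are known targets of the compounds. Rac1, a small GTPase of actin remodelling, was at 237 ± 3.82 CPM (chromosome 5, 143503634 to 143528036, minus strand, GRCm38). Its spread did not pass the chi-square test for variation beyond counting error (adjusted p = 0.0817). The cytokine Il6 (chromosome 5, 30013114 to 30019981, plus strand) had no reads in replicates 1, 3 and 4, where 3 reads correspond to 0.0722, 0.0673 and 0.0870 CPM. It stood at 0.0523 CPM in replicate 2, under the floor of 0.0784 CPM there, and at 0.1005 CPM in replicate 5, above the floor of 0.0754 CPM. These floors cover counting error only. Fkbp5, a glucocorticoid-induced co-chaperone, was at 23.9 ± 1.41 CPM (chromosome 17, 28399094 to 28517527, minus strand) and the neurotrophin Bdnf at 27.7 ± 3.38 CPM (chromosome 2, 109674700 to 109727007, plus strand).

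**Figure D1:**
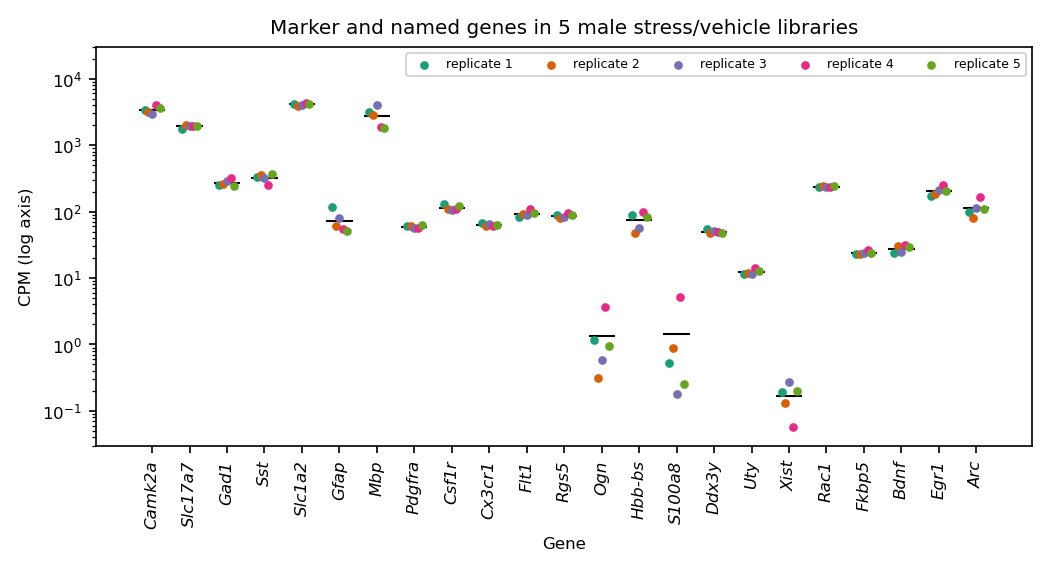
CPM of marker and named genes on a log axis in the 5 libraries of stressed, vehicle-treated males, with a point for each library and a bar at the mean. Ddx3y lies at a mean of 49.9 CPM and Xist at 0.170 CPM.

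Excitatory neurons were represented by the kinase Camk2a (3402 ± 424 CPM), the vesicular glutamate transporter Slc17a7 (1926 ± 94.3 CPM) and Nptx1 (657 ± 68.7 CPM). Inhibitory neurons were represented by the peptide Sst (325 ± 47.1 CPM) and the GABA-synthesising enzyme Gad1 (272 ± 31.3 CPM). Astrocyte genes were led after Slc1a2 by Glul (1799.7 ± 66.2 CPM) and Aldoc (759.8 ± 42.2 CPM), and microglia genes by Csf1r (114 ± 9.88 CPM) and Cx3cr1 (63.1 ± 3.01 CPM). The oligodendrocyte precursor gene Pdgfra was at 59.5 ± 3.21 CPM, the endothelial gene Flt1 at 93.3 ± 10.4 CPM and the pericyte gene Rgs5 at 87.1 ± 5.77 CPM. Of the choroid plexus and ependymal genes, 2 of 14 reached 1 CPM, namely Foxj1 (4.69 ± 1.02 CPM) and Kl (1.53 ± 0.528 CPM), too few for a list score. Per kilobase of exon, Sst reached 450.5 ± 65.3 RPKM and Camk2a 456 ± 56.8 RPKM.

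Among synaptic vesicle genes, Snap25 was at 2605 ± 409 CPM and Dnm1 at 1581 ± 81.1 CPM. The postsynaptic scaffold genes Dlg4 (1048 ± 49.1 CPM) and Shank1 (963 ± 64.4 CPM) followed Camk2a in the glutamatergic list. The metabotropic GABA receptor genes Gabbr1 and Gabbr2 stood at 815 ± 29.8 and 421 ± 37.6 CPM. Neuropeptide genes were led by Vgf (394 ± 39.1 CPM) and Cck (366 ± 35.7 CPM), and monoamine genes included Adra1b (41.8 ± 5.48 CPM) and Maoa (37.4 ± 3.05 CPM). The actin regulators Cyfip2 and Cfl1 were at 981 ± 69.0 and 819.7 ± 55.1 CPM, and the histone deacetylase gene Hdac5 at 230.0 ± 22.2 CPM.

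No unstressed level was set beside the stress-related genes. The immediate early genes Egr1, Homer1 and Arc stood at 204 ± 30.3, 162 ± 15.8 and 113 ± 31.5 CPM. The glucocorticoid-responsive genes Mt1, a metallothionein, and Klf9, a transcription factor, were at 200.2 ± 11.0 and 148 ± 15.02 CPM. Of 30 inflammatory mediators 19 reached 1 CPM, led by the cytokine co-receptor Il6st (75.1 ± 1.84 CPM) and the adhesion molecule Vcam1 (24.5 ± 2.15 CPM). Interferon-stimulated genes were led by Stat2 (30.8 ± 3.05 CPM) and Ifi27 (27.1 ± 2.63 CPM). The chaperone gene Hspa8 (1419 ± 98.4 CPM), the ferritin gene Fth1 (1801 ± 233 CPM), the clock gene Tef (309 ± 25.7 CPM), the sterol enzyme gene Hmgcs1 (389 ± 38.1 CPM), the ATP synthase gene Atp5b (1004 ± 56.4 CPM) and the ribosomal gene Rplp1 (447 ± 13.5 CPM) led their lists.

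A small set of genes varied widely between libraries. Among genes with a mean of at least 1 CPM, the coefficient of variation beyond counting error had a median of 8.25% (quartiles 5.18% and 13.5%) and was over 50% for 58 genes. Of 19239 genes tested, 14308 varied beyond counting error (chi-square test of reads, Benjamini-Hochberg threshold 0.05). The largest spread over genes of like level was in Tnfrsf8, Lcn2, S100a8, Aldh1a3, S100a9, Thbs4, A2m, Slc13a4, Myoc and Fmod. The value for Tnfrsf8 (mean 1.01 CPM) includes 0.0448 CPM in replicate 3, under the floor of 0.0673 CPM for 3 reads there. The acute-phase gene Lcn2 stood at 5.92 CPM in replicate 4 and 0.224 CPM in replicate 3, and the extracellular matrix gene Fmod at 9.86 and 1.03 CPM. The neutrophil gene S100a9 was at 6.55 CPM in replicate 4 and at 0.359 to 0.626 CPM in the others. Thbs4 was at 17.4 CPM in replicate 3 and at 2.44 and 1.81 CPM in replicates 4 and 5.

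**Figure D2:**
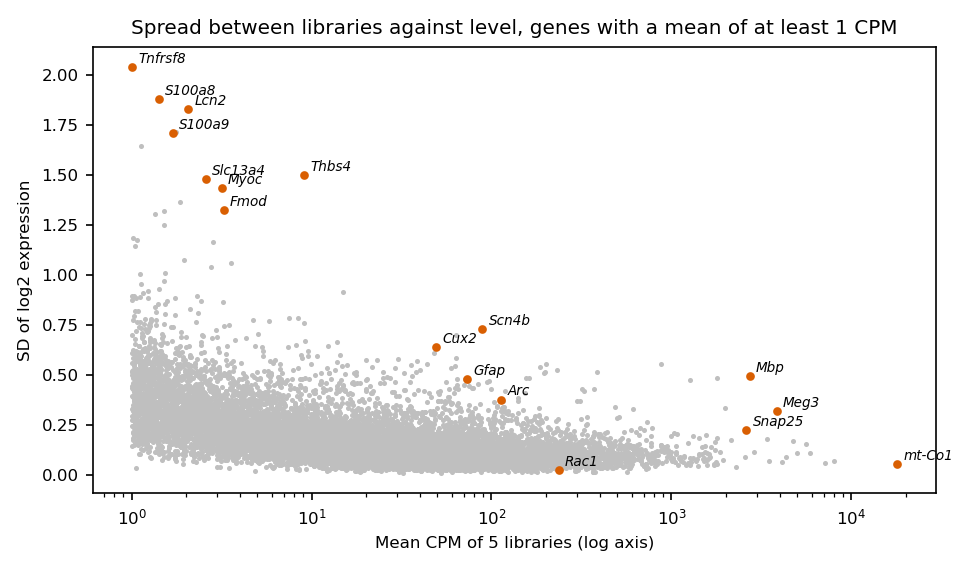
SD of log2 expression between the 5 libraries (vertical axis) against mean CPM (log horizontal axis) for genes with a mean of at least 1 CPM, a grey point per gene and named genes in orange. Mbp, at a mean of 2724 CPM, has an SD of 0.494 and Rac1, at 237 CPM, an SD of 0.0234.

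Myelin genes differed together between libraries. All 28 mature oligodendrocyte genes varied beyond counting error, and 28 of 28 were higher in replicate 3, with the highest list score, than in replicate 4, with the lowest. Mbp, myelin basic protein, stood at 3991 CPM in replicate 3 and at 1857 and 1809 CPM in replicates 4 and 5 (chromosome 18, 82475146 to 82585637, plus strand). Mobp had a mean of 874 ± 322 CPM. The list spanned 2.05-fold between libraries, and the SD of its log2 score was 0.44, above 100% of 10000 random lists matched on expression, whose median SD was 0.028. Oligodendrocyte precursor genes spanned 1.23-fold (SD 0.11, percentile 98.64), with percentile 90.48 without replicate 1.

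The list scores of blood genes and of pericyte, mural and meningeal genes were highest in replicate 4 and lowest in replicate 3, although the mural gene Pdgfrb was lowest in replicate 4 (23.6 CPM) and the pericyte gene Vtn highest in replicate 1 (72.9 CPM). The 7 scored blood genes spanned 3.71-fold (SD 0.73). Among them, S100a8 and S100a9 had means of 1.41 and 1.69 CPM, and of 0.462 and 0.477 CPM without replicate 4. The 5 red blood cell genes alone spanned 1.95-fold (SD 0.46) and were lowest in replicate 2. The 19 pericyte, mural and meningeal genes spanned 1.82-fold (SD 0.33), and this list and the blood list were above 100% of random lists. Without replicate 4 the SDs were 0.46 for blood and 0.20 for mural and meningeal genes. Among members of at least 10 CPM the mural and meningeal SD was 0.19, and too few blood genes remained for a score. The haemoglobin gene Hbb-bs stood at 98.8 CPM in replicate 4 and 48.4 CPM in replicate 2, and the fibroblast gene Ogn at 3.71 and 0.314 CPM. Haemoglobin genes have near-identical copies, so the division of reads between Hba-a1 (53.9 ± 12.1 CPM) and Hba-a2 (9.69 ± 2.59 CPM) is uncertain. Endothelial genes spanned 1.17-fold (SD 0.089, percentile 99.96), with Vwf at 38.3 CPM in replicate 4 and 16.0 CPM in replicate 2.

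Excitatory neuron genes spanned 1.15-fold (SD 0.078, percentile 99.45), although the upper-layer gene Cux2 stood at 76.4 CPM in replicate 4 and 24.1 CPM in replicate 3. Inhibitory neuron genes spanned 1.07-fold (SD 0.034, percentile 56.04), with SDs of 0.010 (percentile 1.5) with scaling to total reads, 0.016 without replicate 1 and 0.057 (percentile 94.13) among members of at least 10 CPM. They included the fast-spiking interneuron gene Pvalb at 64.5 CPM in replicate 4 and 33.0 CPM in replicate 5. Striatal projection neuron genes had their highest list score in replicate 3 (SD 0.16, percentile 99.87), and without that replicate the SD was 0.065 and the percentile 70.03. With no filter on low values the SD was 0.34. Their member Scn4b, a sodium channel subunit, was at 126 and 147 CPM in replicates 3 and 4 and at 45.3 CPM in replicate 5. List scores of GABA receptor (SD 0.12, percentile 100), glutamatergic postsynaptic (SD 0.086, percentile 99.99) and synaptic vesicle genes (SD 0.097, percentile 99.97) were highest in replicate 4. Against the library with the lowest score, 15 of 16, 26 of 30 and 23 of 24 members were higher there. Some members peaked elsewhere, such as Dlg4 and Dnm1 in replicate 5 (1122 and 1650 CPM) and Shank1 in replicate 2 (1041 CPM). Replicate 4 also had the lowest myelin score (-0.49). It stood at 0.795 on the first principal component of genes of at least 1 CPM, whose sign is arbitrary, against -0.419 to 0.185 in the others. The SD was 0.079 for GABA receptors without replicate 4 and 0.064 for vesicle genes without replicate 1. Neuropeptide genes were at percentile 79.34 (SD 0.059), and at 99.46 (SD 0.091) among members of at least 10 CPM, with an SD of 0.16 without a filter. Monoamine genes were at percentile 93.58 (SD 0.076), at 61.54 (SD 0.048) without replicate 1, at 96.17 without replicate 3 and at 96.67 among members of at least 10 CPM.

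List scores of immediate early, glucocorticoid-responsive and clock genes were highest in replicate 4, which also had the highest scores of the blood and the mural and meningeal lists. The immediate early, glucocorticoid and clock SDs were 0.15, 0.14 and 0.12, at percentiles 100, 99.98 and 100. Against the library with the lowest score, 27 of 29, 18 of 22 and 14 of 19 members were higher in replicate 4. Mt1 was highest in replicate 1 (215 CPM, and 209 CPM in replicate 4). Arc was at 165 CPM in replicate 4 and at 80.5 to 113 CPM in the others, and the clock gene Bhlhe40 at 124 CPM against 59.3 to 80.1 CPM. Without replicate 4 the SD was 0.077 for immediate early and 0.055 for clock genes. Among members with a mean of at least 10 CPM, the glucocorticoid list had an SD of 0.063. Inflammatory mediators had an SD of 0.14 (percentile 99.48), and 0.062 (percentile 64.03) among those more abundant members. Heat shock genes were at percentile 95.77 (SD 0.056), and at 76.78 without replicate 4 and 85.96 without replicate 2. Interferon-stimulated and antioxidant genes were at percentiles 69.88 and 79.55 (SD 0.077 and 0.043), and the antioxidant SD was 0.024 without replicate 2 and 0.084 without a filter.

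Astrocyte genes had their highest list score in replicate 1 (SD 0.090, percentile 99.94), where the filament gene Gfap stood at 116 CPM against a mean of 72.8 CPM over libraries. Without replicate 1 the list had an SD of 0.049 at percentile 90.07. Microglia genes were at percentile 98.85 (SD 0.069), and at 93.23 and 91.19 without replicates 1 and 3. Mitochondrially encoded genes (SD 0.14, percentile 99.96) had their highest list score in replicate 4. Of nuclear oxidative phosphorylation genes (SD 0.098, percentile 100), 36 of 36 were higher in replicate 3, with the highest score of that list, than in replicate 1, with the lowest. Cholesterol synthesis genes had an SD of 0.10 (percentile 99.92), and of 0.036 (percentile 63.9) without replicate 3. Nuclear-retained noncoding RNAs had an SD of 0.19 (percentile 100), with Meg3 at 4818 CPM in replicate 2 and 3262 CPM in replicate 5. Ribosomal protein genes (SD 0.043, percentile 71.46), chromatin enzymes (SD 0.044, percentile 88.54), Rac1 and actin regulators (SD 0.036, percentile 53.74), X-linked (SD 0.059, percentile 66.51) and Y-linked genes (SD 0.062, percentile 46.31) were under the 95th percentile as scaled by the deposited sizes. With scaling to total reads, ribosomal genes were at 97.92 and chromatin enzymes at 96.45, and the Rac1 list had an SD of 0.015. The X-linked SD was 0.031 with GC and length trends removed and 0.097 without a filter. The SD was 0.018 for the Rac1 list and 0.031 for Y-linked genes without replicate 1, 0.021 for ribosomal genes without replicate 3 and 0.015 for chromatin enzymes without replicate 4, and ribosomal genes were at percentile 95.37 without replicate 1. In all, 21 of 31 scored lists exceeded that percentile, which describes these libraries and is not a test between conditions.

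**Figure D3:**
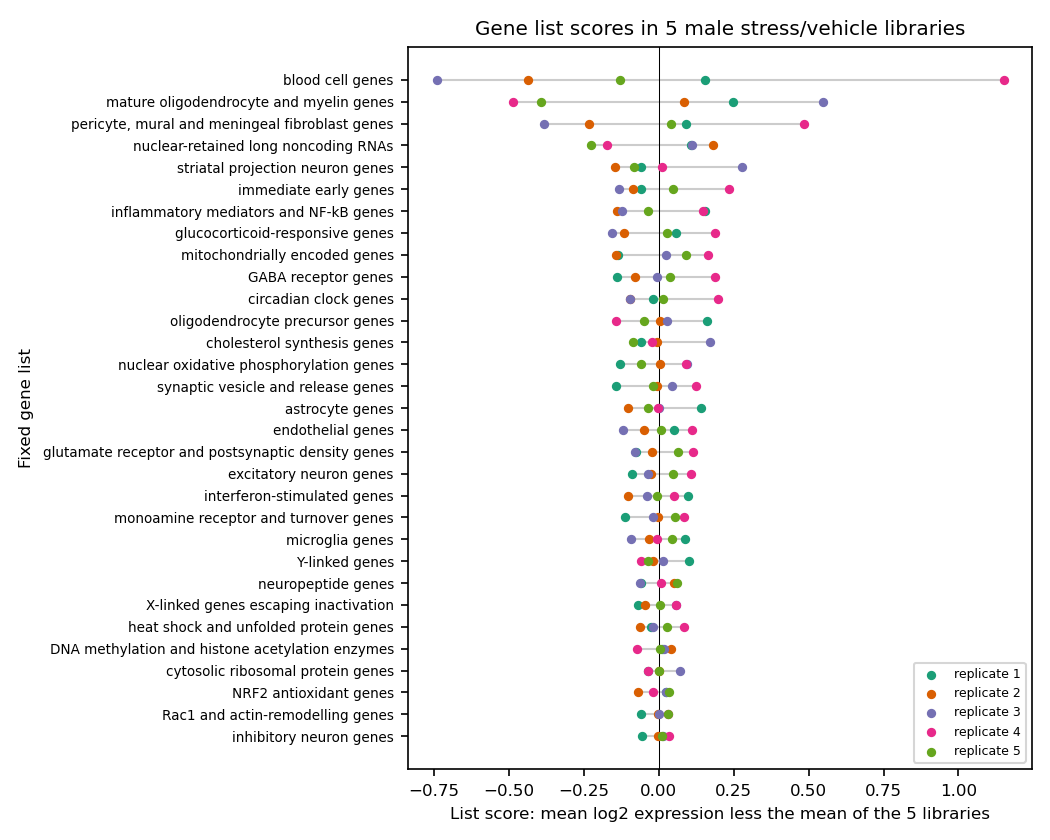
Score of each fixed gene list in the 5 libraries, as the mean log2 expression of its members less the mean over libraries (horizontal axis), a point per library. The myelin list lies at 0.55 in replicate 3 and -0.49 in replicate 4, and the blood list at -0.74 and 1.15.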

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

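The tests of blood and of leptomeningeal genes were chosen only after the result was seen. Among 172 list scores and named genes, 5 genes and no list had a library far from the other 4 by Dixon's ratio, and chance alone gives about 8.6. The neutrophil gene S100a9 stood in replicate 4 at 13.7 times the mean of the others. The lysosomal gene Cd68 in replicate 3 was at 0.697 times the mean of the others, and Tnfrsf8 in the same library at 0.0359 times. Tnfrsf8 stood there at 0.0448 CPM, under the floor of 0.0673 CPM for 3 reads. The pericyte gene Vtn in replicate 1 was at 1.25 times the mean of the others, and mt-Nd4 in the same library at 0.773 times.

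S100a9 was weighed with the neutrophil list, of which 4 of 10 members had a mean of at least 0.5 CPM. Their mean log2 excess in replicate 4 over the other libraries was 2.19, carried by S100a8 and S100a9, while Csf3r stood at 7.25 CPM there and 7.89 CPM in replicate 1. Red blood cell genes had an excess of 0.51, and the gap of 1.67 had a standard error over genes of 0.94, so more blood in the tissue cannot be told apart with so few neutrophil genes. More leptomeninges is a candidate. The 13 genes of the leptomeningeal list had an excess of 0.99, above 100% of matched random lists. The most abundant were Ccn3 (90.1 ± 14.9 CPM) and Igf2 (24.8 ± 8.68 CPM), and 6 of the 13 were in a fixed list already seen. Whether members such as Ccn3 are particular to leptomeninges in this tissue was not tested. An acute inflammatory state may also contribute. The 11 acute-phase genes other than Lcn2 and Lrg1, some of them in fixed lists already seen, had an excess of 0.24 (percentile 98.49). Of these 11 genes, 8 were higher in replicate 4 than the mean of the others. The fixed inflammatory list was not highest there, with a score of 0.146 in replicate 4 and 0.154 in replicate 1. Nor was the interferon list, at 0.049 and 0.097. No biological explanation from the study's groups was tested, because the libraries belong to 1 group.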

How the results depend on the processing

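All alternatives here were chosen after the layout of the table was known. Those planned for the 9 comparisons between groups, the gene list tests between groups and the fold-change comparisons were not run. No paired analysis was possible because only 1 group could be assigned. Genes beyond counting error numbered 12693 with a minimum of 20 reads and 15862 without a filter, and 12646 to 13125 when each replicate was left out. Lists above the 95th percentile numbered 19 to 22 over the settings run. The median coefficient of variation was 7.45% to 8.30% without a replicate. Without replicate 4 the mean was 0.477 CPM for S100a9, 0.462 for S100a8, 1.09 for Lcn2, 1.596 for Fmod and 0.758 for Ogn. Of 371 recomputed list SDs, 31 moved by over 1.5 times, 17 of them without a replicate. The myelin SD lay between 0.36 and 0.50. Scaling to total reads took inhibitory neuron genes to an SD of 0.010 and heat shock genes to percentile 78.61. Heat shock genes were at 92.66 with GC and length trends removed, 75.65 without a filter, 91.12 among members of at least 10 CPM, and 85.96 and 76.78 without replicates 2 and 4. Removing GC and length trends took inhibitory neuron genes to an SD of 0.022. Inflammatory mediators were at 62.03 without a filter. The causes were not tested. Genes with few reads are the least certain.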

Other observations

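The tests of depth, scaling and cortical layers were chosen only after the result was seen. Cortical layer genes differed between the libraries that lay furthest apart in myelin genes. The 10 upper-layer genes, led by Rasgrf2 (84.1 ± 26.9 CPM) and Lamp5 (63.8 ± 31.4 CPM), had a log2 score of 0.49 in replicate 4 and -0.37 in replicate 3. The 10 deep-layer genes, led by Rprm (118 ± 25.1 CPM) and Crym (97.9 ± 16.6 CPM), had -0.50 in replicate 4 and 0.33 in replicate 3. All 10 upper-layer genes were above the mean of the other libraries in replicate 4, and 0 of 10 deep-layer genes were. In each of these lists 2 genes were also in a fixed list.

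The spread of myelin genes (SD 0.44) was weighed against technical sources. Replicates 1 and 5, the closest in total reads (39832257 and 39450601), differed by 0.64 ± 0.036 (standard error over genes) in the myelin score. This error covers the genes of 1 pair of libraries and does not measure variation between libraries. The difference at near-equal depth argues against depth as the whole cause. This test replaced a thinning of the libraries to equal depth, which had moved nothing and so could not decide. Effective sizes were 0.998 to 1.04 times total reads, too near equal for scaling to account for the spread. Scaling to total reads, which gave an SD of 0.45, could hardly have changed it. Removing GC and length trends gave 0.43, so these trends do not account for the spread. RNA quality and handling were not tested and stay open. Nuclear-retained RNA scores split the libraries by sign as myelin scores did, although their order differed. They were 0.11, 0.18 and 0.11 in replicates 1 to 3 and -0.17 and -0.23 in replicates 4 and 5. All 11 scored members were higher in replicate 2, with the highest score, than in replicate 5, with the lowest, but not every member followed the split. The abundant Malat1 was at 558 CPM in replicate 1 and 726 CPM in replicate 4. Peg13 and Kcnq1ot1, singled out after their values were seen, did not follow the split either. In replicate 3, Meg3 and Snhg11 (3443 and 1791 CPM) were under their means of 3842 and 1984 CPM, and Malat1 was above its mean. Gm26917, the most variable member, was at 62.9 CPM in replicate 3 and at 23.2 to 34.8 CPM in the others. The list score of mitochondrially encoded genes was highest in replicates 4 and 5 (0.17 and 0.090), although mt-Nd1 was lowest in replicate 5 (6885 CPM). All 13 members were higher in replicate 4 than in replicate 2, with the lowest score. In replicates 4 and 5, 2200 and 2078 genes had no reads, against 1713 to 1863 in the others. Replicate 4 was also the library with the fewest reads (34565147). Replicate 5 held more reads than replicate 2 (39450601 and 37474364). An unequal share of deep cortex and white matter is a candidate explanation. The layer test first set replicate 3 against the mean of replicates 4 and 5, and was changed to single libraries after its result was seen. Deep less upper layer genes were higher in replicate 3 than in replicate 4 by 1.68, above 100% of matched random list pairs. The layer lists kept Cux2 and Nxph4, each seen before as the most variable member of a fixed list. The percentile therefore rests partly on values already seen. This pair of libraries was chosen as the extremes of the myelin score. Replicate 5, with a myelin score of -0.39, had upper and deep layer scores of 0.090 and -0.040. Replicate 1 had similar layer scores (0.026 and 0.00064) with a myelin score of 0.25. Replicate 2 had layer scores of -0.23 and 0.21 with a myelin score of 0.083. Layer scores thus did not track myelin scores across replicates 1, 2 and 5. Their myelin levels stay open, as does regulation within oligodendrocytes, which was not tested.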
